A study of Mus musculus with 6 samples.

How the data were processed

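RNA had been extracted with Trizol and made into libraries with a stranded total RNA kit, per the labels' protocols. Cells were grown in high-glucose medium with serum and received no treatment, per the labels. The deposited file holds raw counts, which the authors made as whole-number counts per gene for 6 libraries, keyed by NCBI Gene ID with symbol, chromosome and gene type, per the file headers. The aligner STAR 2.5.1b and the genome build mm10 are named in the submitters' processing notes. The counting program, the annotation release and the strand setting are not given in the sources used here, so overlapping and antisense genes, and near-identical genes, could have exchanged reads. Every gene in the table had at least 1 count in some library, and 0 rows named no gene. Column names were matched to the labels by group and number. Coordinates are those of GRCm38, the assembly that mm10 denotes, from a RefSeq gene table in which 94.4% of the table's gene IDs and 97.3% of the tested ones were found.

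Differential expression was tested in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr, libraries were scaled by the trimmed mean of M values (TMM), and a robust quasi-likelihood fit with genotype as the only term was tested two-sided, with Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The common dispersion was 0.0239, a biological coefficient of variation of 15.5%. CPM values use the TMM-scaled library sizes. Fold changes and their standard errors come from that fit, except that genes with 0 to 3 counts over a group were given as a ratio of summed counts with a 95% exact counting interval, or, where that group had 0, against a floor of 3 counts over the group with the lower limit of the interval beside it. Lists of largest changes were ranked by the fitted fold. Such intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Depth was 27323577 to 37841558 counts per library.

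Gene lists (31, holding 786 distinct gene symbols) were fixed before the data were examined: pathways tied to NGLY1, fibroblast programmes and markers of other cell types. The 29 with at least 3 tested genes were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were alternatives. The list of mitochondrially encoded protein genes, of which 0 were in the table, was not analysed here (the mitochondrial ribosomal RNA genes Rnr1 and Rnr2 were in the table), and erythroid markers, with 1 tested gene, had no list test. Genes were named by a rule also fixed before the data were examined: Ngly1; the 8 higher and 8 lower genes with the largest fold change among those past the threshold, with the 6 libraries separated and a mean count of at least 100 in the higher group, leaving out predicted genes, pseudogenes and sex-chromosome dosage genes; the 5 higher and 5 lower with the smallest p under the same conditions; up to 4 members of each list by p; and a set of genes around NGLY1. Genes named beyond this rule are said to have been chosen after their values were seen. Some genes that the rule selects are not reported here.

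Alternatives fixed in advance were DESeq2 1.42.0 size factors, scaling by library totals only, no low-count filter, at least 1 CPM in 3 libraries, the replicate number as a block, the DESeq2 test, limma-voom and each library left out in turn. Alternatives chosen after seeing the data left out structural RNA genes, both libraries numbered 3, or the genes of chromosomes 2, 6, 9, 13, 16, 18, X and Y. These chromosomes are called the shifted ones below. Chromosomes 2 and 18 were left out whole, with the parts whose genes were not shifted. Chromosomes 1, 7, 15 and 17 were kept, although their medians also lay outside the range of the random gene sets described below. The steps were tested on simulated data made from the real means and library sizes of knockout against wild type (15039 genes, 200 changed, 3 libraries each). The edgeR step recovered 49.3% of the 1.5-fold, 82.1% of the 2-fold and 100% of the 4-fold changes, and 9 of its 163 calls were unchanged genes. The camera step found the planted list and 0 others among 30. Changes were planted only in well-counted genes, as many up as down, and each gene was drawn independently. In the real data 60.9% of the tested genes were called, so these rates need not hold there.

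The position comparison used genes of at least 5 CPM on average, windows of 10 Mb holding at least 10 genes, and 10000 random gene sets of the same size per chromosome. The points on chromosomes 2 and 18 were first placed by eye and then replaced by the split in gene order with the least summed absolute deviation from the medians of its sides, with at least 20 genes a side. The outcome of every test was unchanged. Transcript GC content came from the longest GENCODE transcript of each gene, found for 99.2% of these genes, and exon lengths were computed with GenomicRanges 1.54.1.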

Results

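Gene expression was measured by sequencing total RNA from mouse embryonic fibroblasts, cells grown out of dissociated embryos and kept in culture, of C57BL/6 mice. The design compared 3 libraries whose labels give an NGLY1 knockout genotype with 3 wild-type libraries, and asked which genes change when NGLY1 is missing. NGLY1 is the cytosolic peptide:N-glycanase, which strips N-linked glycans from misfolded glycoproteins exported from the endoplasmic reticulum (ER). One of its substrates is the transcription factor encoded by Nfe2l1, which drives proteasome subunit genes. The deposited table gave whole-number counts for 23842 genes. Total counts ran from 33007239 to 37841558 in the knockout-labelled libraries and from 27323577 to 37790710 in the wild-type libraries. Pearson correlation of log2 CPM (counts scaled to library size) across genes, which are not independent replicates, was 0.979 to 0.994 within a group and 0.886 to 0.897 between groups. Libraries of the same group differed by more than sampling noise, with a chi-square per gene of 12.1 to 154. That mean is weighted to genes of large counts and is not a typical spread. In the pair with 154, knockout-labelled replicates 1 and 3, ribosomal RNA genes took 0.215% and 5.25% of the counts. The labels do not say whether the libraries of a group come from separate embryos, lines or dishes, so the p-values measure the spread between these samples, which may be technical.

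Ngly1 (gene ID 59007; chromosome 14, 16249314 to 16311926 in GRCm38) had 618, 420 and 457 counts in the knockout-labelled libraries and 668, 632 and 307 counts in the wild-type libraries. Its level was 14.6 ± 3.11 CPM (SD, n = 3) in the former and 14.6 ± 2.94 CPM (SD, n = 3) in the latter, an adjusted p of 0.99 in edgeR's quasi-likelihood test. The labels do not say which part of the gene was deleted, and a count over the whole gene cannot show whether the transcript lacks a part. The count therefore does not check the genotype, and every direction given here rests on the labels. The ranges of Ngly1 and its neighbour Oxsm, a mitochondrial ketoacyl synthase gene, overlap (16238652 to 16249808 for Oxsm), and since no strand setting is given, reads there could have been assigned to either. Oxsm was 2.10-fold higher in the knockout-labelled libraries (adjusted p = 0.000646). The neighbouring gene Top2b, a DNA topoisomerase gene, was 1.41-fold higher (adjusted p = 0.00148). Rarb, the retinoic acid receptor beta gene that follows it, fell from 170 counts over the wild-type libraries to 3 over the knockout-labelled libraries, a ratio of 54.1 with a counting interval of 18.2 to 265. These 3 counts were all in knockout replicate 2, without which the group had 0.

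The largest differences were close to on and off. Emb (embigin, a membrane glycoprotein) had 1788 counts over the knockout-labelled libraries against 1 over the wild-type libraries, a ratio of 1870 with a counting interval of 335 to 74000. The homeobox gene Six2 and the interferon-inducible gene Ifi213 had 481 and 455 counts against 0, at least 168-fold and at least 159-fold higher against a floor of 3 counts over the group, and 136-fold and 129-fold at the lower 95% limit of counting error. In the other direction, Hand2, a transcription factor of heart and limb development, had 1 count over the knockout-labelled libraries and 2200 over the wild-type libraries, a ratio of 2100 (377 to 83100). Efemp1 (the extracellular matrix protein fibulin-3) fell from 235 ± 10.3 to 0.786 ± 0.17 CPM (SD, n = 3 each), and Aga, a lysosomal enzyme gene, from 47.5 ± 10.2 to 0.147 ± 0.028 CPM. By fold among separated genes with at least 100 counts on average in the higher group, the largest rises also included the potassium channel gene Kcnk5, Cd244, Phf11b (a ratio of 820, 147 to 32400) and Slfn4 (724, 130 to 28600). The largest decreases also included the cathepsin gene Ctsh (a ratio of 734, 131 to 29000), BC034090 (602-fold), Arhgap32, Cpxm2 and Tspan7 (a ratio of 412, 141 to 2000). Ranked by p instead, the carbonic anhydrase gene Car6 (319-fold) and the solute carrier gene Slc43a3 (217-fold) were among the first of the rises. Shroom2 (112-fold), Ildr2 (49.1-fold) and Eps8l2 (21.0-fold) were among the first of the decreases. The single count of the lower group was in wild-type replicate 1 for Emb, in wild-type replicate 3 for Phf11b and Slfn4 and in knockout replicate 3 for Hand2 and Ctsh, so without that library the group had 0 counts. Tspan7 had 0, 2 and 1 counts in the knockout-labelled libraries and Kcnk5 8, 1 and 1 in the wild-type libraries. Without wild-type replicate 1, the log2 fold change of Cd244 moved from 8.44 to 9.27, and without knockout replicate 2, that of Cpxm2 from -8.33 to -9.10.

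Of 15039 genes tested, 9160 (60.9%) passed a false discovery rate of 5%, 4621 of them higher and 4539 lower in the knockout-labelled libraries. A change of at least 2-fold was found for 4286 of them, 2039 higher and 2247 lower. The 3 libraries of each group did not overlap for 67.3% of the tested genes, against 10% by chance. Scaled by library totals only, the median log2 fold change of all tested genes shifted by -0.12 and the share of higher genes went from 50.4% to 42.4%, so directions below are relative to the main scaling.

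**Figure D1:**
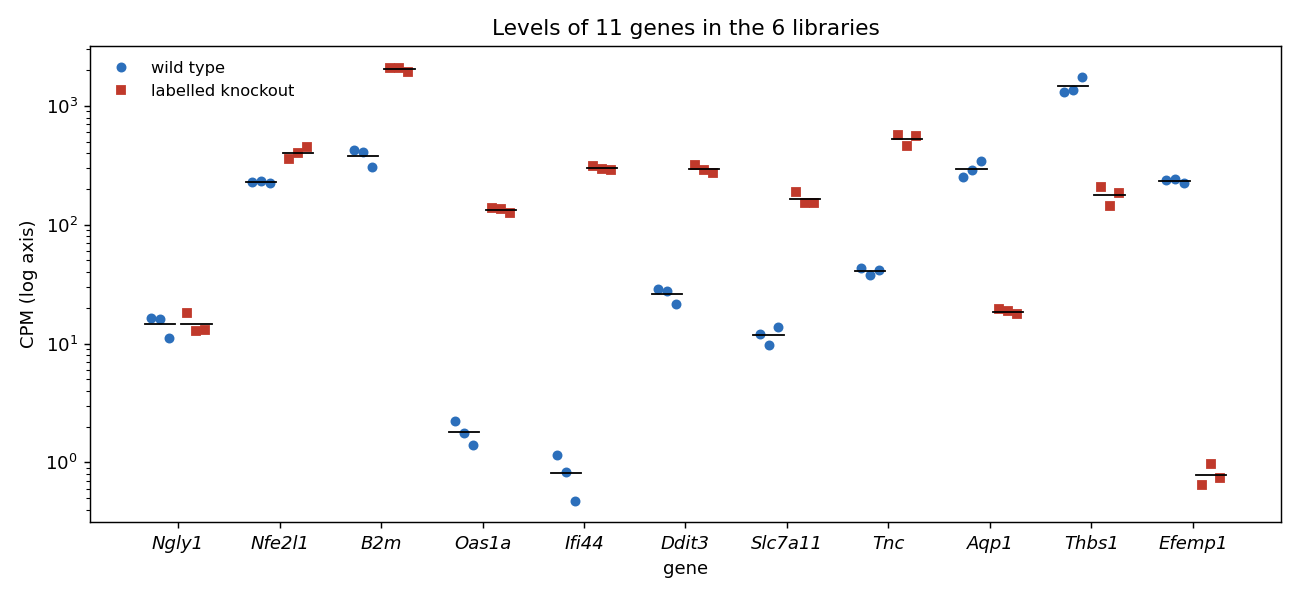
Levels of 11 genes in CPM on a log axis, with a point for each of the 3 wild-type (blue circles) and 3 knockout-labelled libraries (red squares) and a black bar at each mean. Ngly1 overlaps between the groups at 14.6 CPM, while each of the other 10 genes is separated, from Ifi44 (0.818 against 299 CPM) to Efemp1 (235 against 0.786 CPM).

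Interferon-stimulated genes, which encode antiviral effectors and sensors, rose almost as a whole. Of 50 tested, 48 were higher and 0 lower, also when adjusted over the list alone, with a median change of 20.1-fold. Ifi44 rose from 0.818 ± 0.34 to 299 ± 14.6 CPM (SD, n = 3 each) and Xaf1 from 2.73 ± 0.359 to 94.3 ± 6.93 CPM. Oas1a and Oas1g, whose products make the activator of the RNA-degrading enzyme RNase L, rose 72.6-fold and 157-fold, although these near-identical genes could exchange reads. The members that did not pass, named after their values were seen, were Ifit2 (log2 fold change 0.17) and Trim25 (0.07). The list stood apart from all other genes with an adjusted p of 1.13e-19 in the camera test at a preset correlation, and with an adjusted p = 0.856 with an estimated correlation. The cytosolic DNA sensor gene Mb21d1 (cGAS) was 2.49-fold higher and its adaptor gene Tmem173 (STING) 1.52-fold higher, the latter on the part of chromosome 18 whose genes were higher as a group. Mavs, the adaptor of the RNA sensors, had a log2 fold change of 0.20 (adjusted p = 0.0894). Ifnb1, named after its values were seen, had 2, 7 and 1 counts in the knockout-labelled libraries and 0 in each wild-type library, and the 5 interferon genes of types I and III in the table summed to 11 to 25 counts per library.

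Genes of the immunoproteasome and of antigen presentation on MHC class I rose with them: 13 of 15 were higher and 1 lower, and adjusted over the list alone the counts were 13 and 1. B2m, the light chain of MHC class I, rose from 381 ± 63.4 to 2042 ± 88.7 CPM (SD, n = 3 each). Its rise was 5.36-fold and it lies on the distal part of chromosome 2, whose genes were higher as a group. H2-D1 and H2-K1 rose 5.30-fold and 4.57-fold, with reads of this family open to misassignment, and the immunoproteasome subunit gene Psmb8 rose 18-fold. The member that fell was the ER chaperone gene Calr (log2 fold change -0.93), named after its value was seen. The list had an adjusted p of 0.000317, and an adjusted p = 0.856 with an estimated correlation. Inflammatory cytokines and NF-kB targets were higher for 15 of 22 and lower for 3, with the same 15 and 3 adjusted over the list alone. Among them the chemokine genes Cxcl1 and Cxcl5 had log2 fold changes of 6.89 and 5.73 and reached 6.02 and 8.53 CPM. Relb, an NF-kB subunit gene, rose 4.4-fold, and Il1rl1, the interleukin-33 receptor gene, 4.05-fold. Cxcl1 had 1, 1 and 3 counts in the wild-type libraries. The members that fell, named after their values were seen, were Icam1 (log2 fold change -3.08), Cxcl12 (-1.04) and Nfkbia (-0.31). This list had an adjusted p of 0.0068, and an adjusted p = 0.856 with an estimated correlation.

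**Figure D2:**
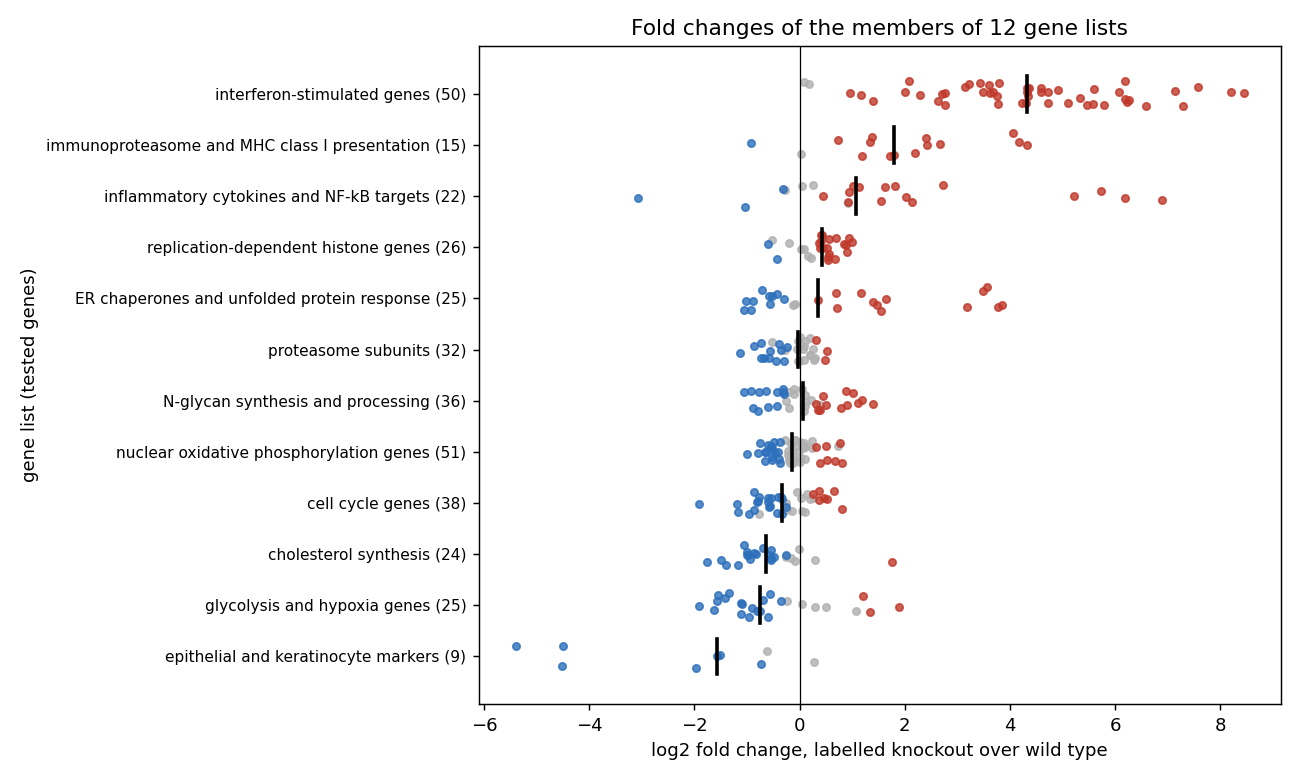
Log2 fold change (knockout-labelled over wild type) of each tested member of 12 gene lists, with higher genes past 5% false discovery rate in red, lower ones in blue, others in grey and a black bar at each list's median. The interferon-stimulated genes lie furthest to the right (median 4.33), and the medians of cholesterol synthesis (-0.64), glycolysis and hypoxia (-0.76) and epithelial markers (-1.57) lie to the left.

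Cholesterol synthesis genes were lower for 18 of 24 and higher for 1, with a median log2 fold change of -0.64. Adjusted over the list alone, 19 were lower and 1 higher, and without knockout replicate 2, 14 were lower and 2 higher. Nsdhl, Mvd and Sc5d, enzymes of the pathway, were 3.39-fold, 2.82-fold and 2.65-fold lower, with Nsdhl on chromosome X and Sc5d on chromosome 9, whose genes were lower as groups. The list had an adjusted p of 0.00111, and an adjusted p = 0.914 with an estimated correlation. Glycolysis and hypoxia genes were lower for 17 of 25 and higher for 3 (17 and 5 adjusted over the list alone), with 5 higher without wild-type replicate 3 and 6 higher without both libraries numbered 3. The glycolytic enzyme genes Pfkl and Tpi1 fell from 334 ± 23.1 to 108 ± 12.1 CPM and from 832 ± 105 to 284 ± 34.0 CPM (SD, n = 3 each), the latter on chromosome 6, whose genes were lower as a group. Pfkp, another phosphofructokinase gene, rose 2.53-fold and Ndrg1, a hypoxia-responsive gene, 3.71-fold. The other member that rose was Vegfa (log2 fold change 1.21), named after its value was seen. The list had an adjusted p of 0.0182, and an adjusted p = 0.914 with an estimated correlation.

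The ER chaperone and unfolded protein response list went both ways: 13 of 25 genes were higher and 10 lower, also adjusted over the list alone, and the list did not stand apart (adjusted p = 0.4). The stress-induced regulators Ddit3 (CHOP), Ppp1r15a, Trib3 and Chac1 rose 11.2-fold, 11.9-fold, 13.6-fold and 9.04-fold, with Trib3 and Chac1 on the distal part of chromosome 2. Ddit3 went from 26.0 ± 3.83 to 293 ± 21.4 CPM (SD, n = 3 each). Among the chaperone genes, chosen after their values were seen, Calr, Pdia6 and Hsp90b1 had log2 fold changes of -0.93, -0.88 and -0.58, and Hspa5 (BiP) one of 0.72, all past the threshold.

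The genes closest to NGLY1 changed singly more than as groups. Since 60.9% of all tested genes were called, a single call is not particular to them. Nfe2l1 rose 1.76-fold, from 228 ± 3.36 to 402 ± 46.0 CPM (SD, n = 3 each; adjusted p = 9.12e-05), and Nfe2l2, encoding the antioxidant regulator NRF2, 2.30-fold. Ddi2, the protease that cleaves the Nfe2l1 product, was 1.36-fold higher (adjusted p = 0.0177). That call was lost without knockout replicate 3, wild-type replicate 1 or wild-type replicate 2 (adjusted p = 0.064, 0.0561 and 0.0703). Engase, the other cytosolic deglycosylating enzyme, rose 2.05-fold. Vcp, the ATPase that extracts proteins from the ER membrane, was 2.13-fold lower, Rad23b, a proteasome shuttle gene, had a log2 fold change of 0.16 (adjusted p = 0.236), and the unrelated respiratory factor gene Nrf1 one of 0.08 (adjusted p = 0.534; -0.04 when scaled by library totals only). Rad23b passed without wild-type replicate 3 (adjusted p = 0.0297). Aqp1, a water channel gene, fell 16-fold, from 296 ± 46.8 to 18.6 ± 0.87 CPM. Of 4 aquaporins tested, 3 were lower and 0 higher, and the same 3 adjusted over the list alone (list adjusted p = 0.106). The calls of Aqp5 (1.29-fold lower) and Aqp11 (3.01-fold lower, under 1 CPM) were each lost when single libraries were left out, with an adjusted p of 0.052 to 0.118 for Aqp5 and 0.07 to 0.128 for Aqp11 in those cases. Both were also lost in the DESeq2 test (adjusted p = 0.0521 and 0.0626), and Aqp5 with no low-count filter (0.0761) and without both libraries numbered 3 (0.0982).

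Of 32 proteasome subunits, 3 were higher and 12 lower (3 and 10 adjusted over the list alone; list adjusted p = 0.476), with the smallest p for Psmd2, 2.20-fold lower, and Psmd4, 1.67-fold lower. Without wild-type replicate 3, 9 were higher and 10 lower, without knockout replicate 2, 1 and 8, without wild-type replicate 1, 1 and 14, and without both libraries numbered 3, 11 and 10, which turns the balance. ER-associated degradation and peptide N-glycanase cofactor genes were higher for 8 of 24 and lower for 7, also adjusted over the list alone (list adjusted p = 0.863), with Fbxo2, which recognises N-glycans, 10.6-fold lower, Sel1l 1.92-fold higher and Ube2g2 2.39-fold higher. The balance of this list turned to 6 higher and 9 lower scaled by library totals only. It was 8 and 9 with at least 1 CPM in 3 libraries and 6 and 8 without wild-type replicate 1. With no low-count filter, with the replicate number as a block and in the DESeq2 test it was even (8 and 8), as without knockout replicate 1 (7 and 7). N-glycan synthesis genes split evenly, 12 higher and 12 lower of 36 (14 and 12 adjusted over the list alone; list adjusted p = 0.934), among them Alg8 (2.64-fold higher) and Man1a2 (2.09-fold lower). Scaled by library totals only, 9 were higher and 15 lower, and without knockout replicate 2, 11 and 7. NRF2 antioxidant and glutathione genes were higher for 8 of 26 and lower for 12 (9 and 13 adjusted over the list alone; list adjusted p = 0.671, with a median of -0.35 and a mean of 0.02 on the log2 scale). In this list the cystine transporter gene Slc7a11 rose 14.0-fold and the heme oxygenase gene Hmox1 2.73-fold, while the peroxiredoxin gene Prdx1 was 2.08-fold lower. Mitophagy and mitochondrial dynamics genes were higher for 7 of 23 and lower for 11, also adjusted over the list alone (list adjusted p = 0.604), with the autophagy receptor gene Sqstm1 2.22-fold higher and Fundc1 2.49-fold lower. Nuclear oxidative phosphorylation genes were higher for 7 of 51 and lower for 18, also adjusted over the list alone (list adjusted p = 0.157). With library totals only, 6 were higher and 27 lower. The genes with the smallest p, Ndufa4, Cox7b, Atp5j and Uqcrc1, were all lower and lie on chromosomes 6, X, 16 and 9, whose genes were lower as groups. Autophagy and lysosome genes were higher for 11 of 30 and lower for 6, also adjusted over the list alone (list adjusted p = 0.469), including Npc1, 2.40-fold higher, and Atg9b, 18.3-fold lower. Without the shifted chromosomes, 4 of 19 of these were higher and 5 lower.

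Of the fibroblast programmes, collagens and extracellular matrix genes were higher for 12 of 33 and lower for 9 (12 and 10 adjusted over the list alone; list adjusted p = 0.788). The list's median log2 fold change was -0.08 while its mean of 0.14 and its test pointed up, and scaled by library totals only 11 were higher and 13 lower. Tenascin C (Tnc) rose from 40.7 ± 2.91 to 530 ± 58.2 CPM and the gelatinase gene Mmp2 from 17.9 ± 4.20 to 246 ± 13 CPM, while thrombospondin 1 (Thbs1) fell from 1471 ± 234 to 179 ± 32.6 CPM (SD, n = 3 each). Thbs1 lies on chromosome 2 within 1 Mb before the point from which its genes were shifted. BMP and TGF-beta signalling genes were higher for 8 of 24 and lower for 8, also adjusted over the list alone (list adjusted p = 0.812; median -0.17, mean 0.03). The BMP antagonist gene Grem1 rose 23.0-fold and the TGF-beta receptor gene Tgfbr2 was 2.79-fold lower. Smooth muscle and myofibroblast contractile genes were higher for 6 of 16 and lower for 5, also adjusted over the list alone (list adjusted p = 0.999; median 0.20, mean -0.37), with Actg2 16.4-fold higher, Cnn1 69.0-fold lower and Mylk 3.00-fold lower. This balance was not stable: scaled by library totals only or with no low-count filter, 4 were higher and 5 lower, and with at least 1 CPM in 3 libraries, 5 and 5. Without knockout replicates 1, 2 and 3 in turn the counts were 3 and 4, 5 and 5, and 5 and 5. Without wild-type replicates 1, 2 and 3 in turn they were 4 and 6, 3 and 5, and 8 and 5. Leaving out both libraries numbered 3 gave 7 and 5. Heat shock and immediate early genes were higher for 15 of 28 and lower for 8, also adjusted over the list alone (list adjusted p = 0.338). Egr1, on the shifted part of chromosome 18, rose 12.2-fold and Ier2 5.79-fold, and the phosphatase gene Dusp1 was 5.58-fold lower. The p53 target and senescence genes were higher for 10 of 22 and lower for 6 (11 and 7 adjusted over the list alone; list adjusted p = 0.539), with Sesn2, Bbc3 and Pmaip1 4.15-fold, 5.97-fold and 5.59-fold higher.

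Cell cycle genes were lower for 20 of 38 and higher for 7 (21 and 8 adjusted over the list alone), a list adjusted p of 0.104. Only 4 were higher when scaled by library totals only, beside 21 lower, and without knockout replicate 2, beside 17 lower. The mitotic genes Ccnb2, Cenpf, Kif23 and Kif11 were 3.78-fold, 2.30-fold, 2.24-fold and 1.95-fold lower, Ccnb2 and Kif23 on chromosome 9. Replication-dependent histone genes were higher for 18 of 26 and lower for 2, also adjusted over the list alone, with a median log2 fold change of 0.43 and an adjusted p of 0.0149, and an adjusted p = 0.914 with an estimated correlation. Hist1h1a, Hist1h2ac, Hist1h2ae and Hist1h3c rose 1.84-fold to 2-fold, although histone genes resemble each other enough to exchange reads. On chromosome 13, whose genes were higher as a group, lie 21 of the 26, with a median of 0.45, and the 5 on chromosome 3 had a median of 0.02. Without the shifted chromosomes the histone list no longer passed (adjusted p = 0.742). The members that fell, named after their values were seen, were Hist1h1b (-0.61) and Hist1h4b (-0.43 on the log2 scale). Hox genes, which record the position of a cell along the body, were higher for 9 of 25 and lower for 14 (10 and 14 adjusted over the list alone; list adjusted p = 0.29). All 6 tested on chromosome 11 (HOXB) were higher, 5 of them under 1 CPM in both groups, and 10 of 11 on chromosome 6 (HOXA) were lower. HOXD, on chromosome 2, went both ways, with 2 of 7 higher (Hoxd8 and Hoxd9, named after their values were seen, with log2 fold changes of 1.26 and 0.64) and 4 lower. This cluster lies before the point from which the genes of chromosome 2 were shifted. Hoxa13 fell 40.6-fold to 0.128 CPM, Hoxa9 was 4.03-fold lower, Hoxd11 9.33-fold lower and Hoxd13 2.41-fold lower. The direction of the list depended on which clusters were counted. Leaving out the shifted chromosomes removes HOXA and, with the whole of chromosome 2, also the unshifted HOXD. The remaining 7 genes were then higher (median 2.37, adjusted p = 0.00312), while the whole list had an adjusted p = 0.914 with an estimated correlation. With at least 1 CPM in 3 libraries, 2 of 15 were higher and 12 lower (adjusted p = 0.0046).

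Further lists held markers of other cell types that such a culture could hold. Epithelial and keratinocyte markers were lower for 7 of 9 and higher for 0, also adjusted over the list alone (list adjusted p = 0.0174, and an adjusted p = 0.856 with an estimated correlation; 0.097 with no low-count filter). Krt19 fell from 74.1 ± 28.7 to 24.8 ± 4.4 CPM (SD, n = 3 each), and Perp, also a p53 target, from 6.12 ± 2.38 to 0.262 ± 0.236 CPM. Krt7 had 141 counts over the wild-type libraries and 3 over the knockout-labelled libraries, a ratio of 44.9 (15.1 to 220). The 3 counts of Krt7 were all in knockout replicate 1, without which the group had 0 and Perp moved from -4.51 to -5.34 on the log2 scale. Of 5 macrophage and leukocyte markers tested, 3 were higher and 1 lower, also adjusted over the list alone (list adjusted p = 0.393). They were Mpeg1 (5.97 CPM), Cd53 (1.28 CPM) and Cd14 (6.95 CPM) on the one hand and Coro1a (0.381 CPM) on the other, as levels in the knockout-labelled libraries. Cd14 lost its call without knockout replicate 3 (adjusted p = 0.0501). Neural and glial markers were higher for 3 of 7 and lower for 1 (4 and 1 adjusted over the list alone; list adjusted p = 0.29), with Tubb3 2.79-fold higher at 36.6 CPM, Sox2 7.72-fold higher at 2.11 CPM, Stmn2 at 3.32 CPM and Erbb3 2.75-fold lower. Without wild-type replicate 3, 4 of these were higher and 2 lower, and without both libraries numbered 3, 5 and 2. Endothelial markers were higher for 2 of 6 (Flt1 and Kdr) and lower for 1 (Eng), with 2 and 0 adjusted over the list alone (list adjusted p = 0.812). Kdr lost its call without knockout replicate 3, wild-type replicate 1 or wild-type replicate 2 (adjusted p = 0.05 to 0.0551), and Eng without any library but wild-type replicate 3 (0.0936 to 0.161). The call of Eng was also lost with no low-count filter (adjusted p = 0.127), in the DESeq2 test (0.0838), without structural RNA genes (0.0515) and without both libraries numbered 3 (0.0609). Endothelial counts turned to 2 higher and 3 lower with no low-count filter and in the DESeq2 test, and were even without knockout replicates 2 and 3 and wild-type replicates 2 and 3 (2 and 2, 1 and 1, 1 and 1, and 2 and 2). Adipocyte markers were higher for 2 of 4 (Dgat2, 23.5-fold to 49.1 CPM, and Pparg, 2.39-fold) and lower for 1 (Fabp4), cartilage and bone markers higher for 2 of 7 (Spp1, from 290 to 1695 CPM, and Sox9, 2.53-fold) and lower for 2 (Matn3 and Phex), and skeletal muscle markers higher for 1 of 5 (Des) and lower for 1 (Myl4), all with the same counts adjusted over the list alone. Without knockout replicate 2, knockout replicate 3 or wild-type replicate 1, 2 skeletal muscle markers were lower. Des moved from 2.90 to 3.66 on the log2 scale without wild-type replicate 1. Their list adjusted p was 0.531, 0.92 (median -0.02 against a test pointing up) and 0.661. The single erythroid marker tested, Klf1, was under 1 CPM and lower (log2 fold change -2.48, adjusted p = 0.037), also adjusted over the list alone. That call was lost without knockout replicate 1, knockout replicate 3 or wild-type replicate 2 (adjusted p = 0.129, 0.121 and 0.0969), and in the DESeq2 test (adjusted p = 0.0636). All 6 counts of the knockout-labelled group were in knockout replicate 2.

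In all, 7 of 29 tested lists stood apart at 5% false discovery rate with the preset correlation, 4 higher and 3 lower, and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. Other splits of the 6 libraries gave up to 9 lists.

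Fold changes also followed position along the genome, a comparison chosen after the data were seen. Over 10379 genes of at least 5 CPM with a location, the median log2 fold change was 0.07. It was 0.55 on chromosome 13 (419 genes, 80.2% of them above the median of all genes) and -0.33, -0.31 and -0.30 on chromosomes 6, 9 and 16. On chromosome 2 it was 0.00 before 118.9 Mb and 0.75 from there on, and on chromosome 18 it was 0.83 before 62.1 Mb and -0.02 beyond. These medians for chromosomes 13, 6, 9 and 16, and those for whole chromosomes 2 (0.34) and 18 (0.59), lay outside the range of 10000 random gene sets of the same size. So did those of chromosomes 1 (0.24), 7 (0.25), 15 (0.25), 17 (-0.08) and X (-0.14). Random sets do not keep neighbouring genes together, so neighbours that vary together could also take a median outside this range. Of the genes named above, Emb and Pfkp lie on chromosome 13, Npc1 and Cd14 on the raised part of chromosome 18, Aqp1 and Cxcl12 on chromosome 6, Arhgap32, Cnn1, Ctsh, Icam1 and Tgfbr2 on chromosome 9, Mylk and Psmd2 on chromosome 16, and Fundc1, Phex, Shroom2 and Tspan7 on chromosome X, each changed in the direction of its chromosome, although Phex and Shroom2 lie in a 10 Mb window with a median of 0.185. Against that direction, Actg2 and Pparg on chromosome 6 and Mb21d1 on chromosome 9 were higher, and Hist1h1b and Hist1h4b on chromosome 13 lower. Hand2 and Aga lie together on chromosome 8, in the 10 Mb window from 50 Mb. Its 11 genes had a median of -0.928, the lowest of all windows, so these 2 decreases need not be separate. Chromosome 8 as a whole (-0.06) lay within the range of random sets. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, described apart from the other named genes, fell by 1.54, 1.02, 1.68 and 1.74 on the log2 scale. Xist had 2 to 17 counts per library.

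**Figure D3:**
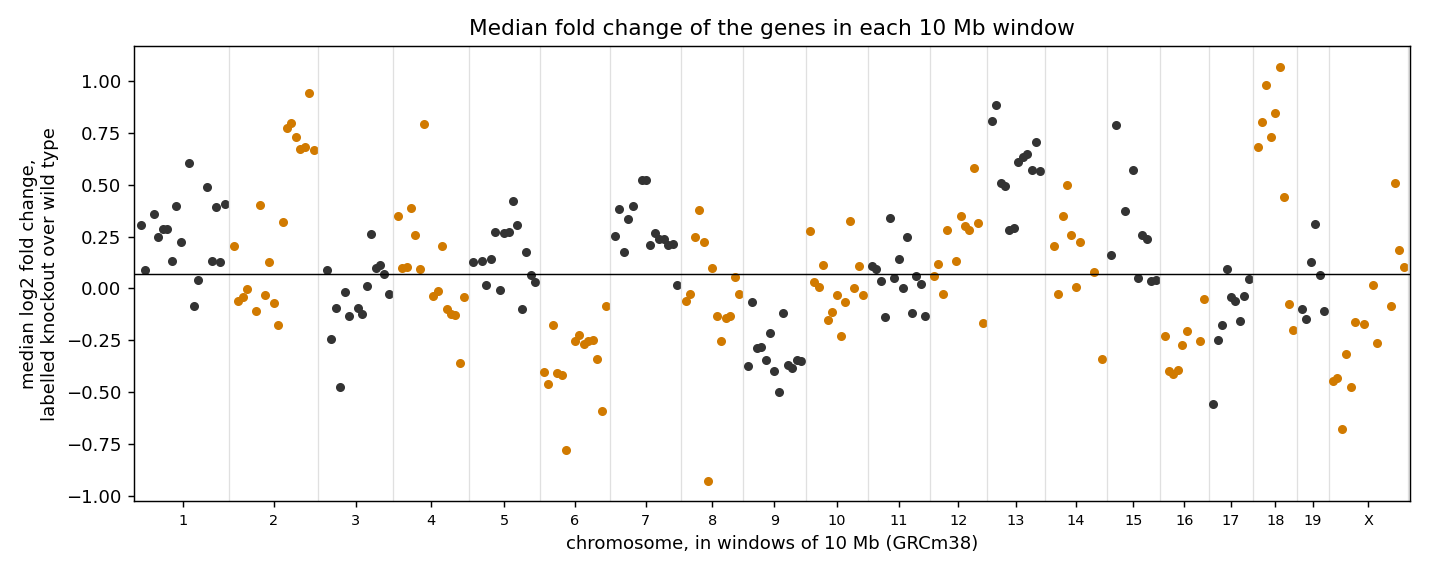
Median log2 fold change (knockout-labelled over wild type) of the genes in each 10 Mb window with at least 10 genes, along chromosomes 1 to 19 and X, with alternating colours for neighbouring chromosomes and a line at the median of all genes (0.07). All 12 windows of chromosome 13 lie above the line, between 0.28 and 0.89, and all 13 windows of chromosome 9 lie below it.

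RNA classes differed as well. Protein-coding genes were higher for 4347 of 12513 and lower for 3718 (median log2 fold change 0.04), whereas noncoding RNA genes were higher for 203 of 1365 and lower for 482 (median -0.44), and pseudogenes higher for 52 of 996 and lower for 281 (median -0.72). Genes with at least 1 count numbered 18916, 19015 and 19087 in the knockout-labelled libraries and 20377, 19990 and 19687 in the wild-type libraries. Reads of the ribosomal RNA genes Rn18s-rs5, Rnr1 and Rnr2 took 0.215%, 0.984% and 5.25% of the counts in knockout-labelled replicates 1, 2 and 3, and 1.55%, 1.93% and 3.95% in the wild-type replicates. The library numbered 3 had the highest share in each group. Without both libraries numbered 3, an alternative chosen after the data were seen, 9847 genes passed, 5043 of them higher.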

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

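The alternatives without structural RNA genes, without both libraries numbered 3 and without the shifted chromosomes were chosen after the data were seen. The count of genes past 5% false discovery rate was 8166 to 10203 when each library was left out, and 8320 to 9847 under the other alternatives except the last, without the shifted chromosomes. There 6014 genes passed, 3044 higher and 2970 lower, 2803 of them changed at least 2-fold, of only 10282 tested. Of the 9160 genes, 86.4% to 99.9% of those tested kept their call and direction in each alternative, and 0 were called in the opposite direction. The highest count, 10203, came without wild-type replicate 3. The counts with each library left out show how far the calls depended on single libraries, and depth was not varied.

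Same-numbered libraries of the groups had deviations correlated at 0.10, 0.01 and 0.21, so the labels' numbers were not taken to pair them, and knockout-labelled replicate 1 correlated best with wild-type replicate 2 (0.15). With the replicate number as a block, 9253 genes passed, 4690 higher and 4563 lower, 4270 of them changed at least 2-fold, with 7 lists. Among the named genes the block ended the calls of Aqp11 (adjusted p = 0.054) and Eng (0.0795) and changed no other call.

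Ngly1 was near 0 and far from the threshold throughout. Its log2 fold change was -0.0031 in the main test, 0.02 with no low-count filter, 0.00085 with the replicate block, 0.01 in the DESeq2 test, 0.0048 without structural RNA genes and -0.18 to 0.10 with single libraries left out. Ngly1 changed sign in 8 of these alternatives. Over the other 151 named genes and all alternatives, 2307 values kept their direction and side of the threshold, 33 lost the call, 7 gained it and 4 changed sign. Those 4 changes of sign were in genes not past the threshold: Plin4 (-0.01 without both libraries numbered 3, -0.08 to 0.54 with single libraries left out), Acta1 (-0.72 to 0.20 with single libraries left out) and Nrf1 (-0.04 scaled by library totals only). The cause was not tested.

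Of the 29 lists, 0 passed with an estimated correlation and 18 in fry's directional test, which does not compare a list with other genes. Under the alternatives with the preset correlation, the interferon-stimulated, class I presentation, inflammatory, cholesterol and glycolysis lists passed in all 14. The histone list failed without the shifted chromosomes, which leaves 5 of its genes, and the epithelial list with no low-count filter. Cell cycle genes passed in 2 of 14 and aquaporins in 3 of 13. Hox genes, not past the threshold in the main test, passed as lower with at least 1 CPM in 3 libraries (adjusted p = 0.0046) and as higher without the shifted chromosomes (adjusted p = 0.00312), which leaves 7 of them, from the HOXB and HOXC clusters (the whole list had an adjusted p = 0.914 with an estimated correlation). Directions changed only for lists not past the threshold in the main test, given here as medians of log2 fold change. They were N-glycan synthesis (-0.06 with library totals only, 0.03 with at least 1 CPM in 3 libraries), Hox genes (0.98 with no low-count filter, 2.37 without the shifted chromosomes), and endothelial markers (-0.64 with no low-count filter, 0.01 without both libraries numbered 3, -0.36 to 0.53 with single libraries left out). Cartilage markers were at -0.45 with no low-count filter and at -0.41 to 0.07 with single libraries left out. For smooth muscle genes, whose main p was near 1, the test pointed down at medians of 0.20 in fry (adjusted p = 0.0184), 0.20 with DESeq2 size factors, 0.08 with no low-count filter, 0.17 with at least 1 CPM in 3 libraries, 0.21 without structural RNA genes and 0.09 to 0.22 with single libraries other than wild-type replicate 3 left out (0.30 without that one, pointing up). Except where genes were removed, the cause was not tested.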

Other observations

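Cytosolic aminoacyl-tRNA synthetase genes, for the enzymes that load amino acids onto transfer RNA, were picked after the data were seen from gene families whose counts had been looked at. Of 21 tested, 16 were higher and 1 lower in the knockout-labelled libraries, with a median log2 fold change of 1.08, and the same counts held with library totals only. Lars, Tars and Wars, for leucine, threonine and tryptophan, had log2 fold changes of 2.42, 2.13 and 2.05, and Qars, for glutamine, one of -0.96. Without the shifted chromosomes, 11 of 15 were higher and 0 lower, with a median of 0.84. The family was not tested as a list.

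Of the tests below, the one of GC content was fixed before its result was seen, with the points on chromosomes 2 and 18 then placed by eye and moved by under 1 Mb since, and the others were chosen after it.

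The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 9160 genes, 4621 higher, 4539 lower and 4286 with at least a 2-fold change, and the highest of the other splits gave 0 for each, so for each of these counts 1 split of 10 was as large. For the gene lists, 5 of 10 splits gave at least the 7 lists of the real one, the highest other split 9. The interferon-stimulated genes passed in all 9 of the other splits, none of which balances the groups, with a lowest adjusted p of 5.12e-11 against 1.13e-19 in the real split.

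For the rise of the interferon-stimulated genes, 3 other explanations were weighed, the first being white blood cells in the cultures. These would bring their abundant transcripts, and the summed level of such genes, chosen after the data were seen, argues against them. Of the 5 genes Ptprc, Coro1a, Laptm5, Tyrobp and Lyz2, 3 are in the table. Their sum was at most 0.472 CPM in a knockout-labelled library and 0.841 to 1.93 CPM in the wild-type libraries. The interferon-stimulated genes summed to 7434 to 8374 CPM in the former group and 612 to 859.8 CPM in the latter. The sum of those 3 genes was mostly Coro1a, with 0.442 of the 0.472 CPM in knockout-labelled replicate 1. It therefore rests largely on 1 gene, which fell. Of the fixed macrophage and leukocyte markers, 3 of 5 were higher in the knockout-labelled libraries: Mpeg1 (51.6-fold), Cd53 and Cd14. They reached 5.97, 1.28 and 6.95 CPM, and so went the other way from Coro1a. Such levels of single genes cannot be set against a sum over the whole interferon-stimulated list. Copy number of the listed genes themselves is also argued against. The 40 listed genes outside the shifted chromosomes had a median log2 fold change of 4.32. A changed copy number of a regulator acting on genes elsewhere was not tested. It stays open whether the knockout-labelled libraries share a line or culture that differs from the wild type in more than NGLY1: within-group correlation was at least 0.979 and no label names the embryo, so genotype and line cannot be told apart, and an effect of NGLY1 loss is an untested candidate explanation.

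The shifts along chromosomes may reflect copy number differences between the cultures, as a hypothesis found and tested on the same data. In 6 stretches (chromosomes 13, 6, 9 and 16, chromosome 2 from 118.9 Mb and chromosome 18 before 62.1 Mb, points set from the same values), 100% of the 10 Mb windows shifted the way of their stretch. These stretches were picked for their shift. Chromosome X, whose genes were lower as a group, had 10 windows lower and 3 higher. Chromosome Y was not part of the window comparison. Its genes Ddx3y, Eif2s3y, Kdm5d and Uty had log2 fold changes of -1.54, -1.02, -1.68 and -1.74. Chromosomes 1, 7, 15 and 17, also outside the range of random sets, had windows on both sides too. The median in the 10 Mb before and after the points on chromosomes 2 and 18 went from 0.00 to 0.77 and from 1.11 to 0.10. GC content of the transcripts is argued against, since at least 0.93 of the shift was left in 3 stretches after a trend on GC was removed. These were chromosome 13, distal chromosome 2 and proximal chromosome 18. In them at least 80.2% of the genes lay above the median of all genes. In the lowered stretches, chromosomes 6, 9 and 16, at most 30.4% did, with a 95% upper limit of at most 35.7%. That limit treats genes as independent draws, which neighbouring genes need not be. Shares on the side of the shift also follow in part from picking the stretches by their medians. As a description, the shifts were spread over most genes of each stretch. The stretches were picked by their medians, which a few strongly changed genes hardly move, so such genes were not tested as an explanation. DNA copy number was not measured here, and regulation over long domains was not tested.

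Genes of low level were lower in the knockout-labelled libraries in each RNA class: below 1 CPM the median log2 fold change was -0.48 for protein-coding genes, -0.61 for noncoding RNA genes and -0.76 for pseudogenes, against 0.07 for protein-coding genes over 64 CPM. Library depth is argued against for genes of few counts. The shallowest library, wild-type replicate 3 with 27323577 counts, had 727 CPM in the 8954 genes with under 60 counts in all. That was above the 435 to 472 CPM of the knockout-labelled libraries. The 8954 genes include those too low to be tested, so they are not the set of tested genes behind the medians above. Uniform background such as genomic DNA is argued against too, provided that genes absent from the table had 0 counts. Receptor and keratin-associated gene families that fibroblasts are not known to use, 1809 genes with 5777 kb of exon, were compared with 993 low-level protein-coding genes. They differed between the groups by 0.329% of the median difference per kb in the latter. Only 55 of the 1809 are in the table, with 161 to 236 counts per library, while the exon length is that of all. If the others were never counted, the background is understated. Differences in nuclear or unspliced RNA, and a biological difference between the groups, stay open and untested.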
